A study of Homo sapiens with 4 samples.

How the data were processed

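Binding of the La-related protein LARP4 to RNA was measured in HEK293 cells, a human embryonic kidney line, by enhanced crosslinking and immunoprecipitation (eCLIP). In this assay ultraviolet light links proteins to the RNA they touch, an antibody recovers the protein with its RNA, and the recovered fragments are sequenced beside a size-matched input, which is RNA from the same part of the gel without the antibody step. Per the labels' protocols, the cells of each biological replicate received 400 mJ/cm2 at 254 nm. The samples formed 2 groups, LARP4 eCLIP with 2 replicates and size-matched input with 2 replicates. Group and replicate number came from the sample titles. The LARP4 eCLIP replicates each had a list of clusters. The inputs entered only as the denominator of the values in those lists.

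Per the labels' protocols, reads were processed with the authors' eCLIP pipeline. UMI-tools 1.0.0, cutadapt 1.14, STAR 2.7.6a and SAMtools 1.6 and the genome build hg19 are named per the submitters' processing notes. The peak caller, its thresholds, the scaling for depth, the input paired with each replicate and the treatment of clusters with no input reads are not given in the sources used here. The authors deposited a list of stranded intervals for each replicate and 1 list for the whole series. For each interval the lists hold the authors' −log10 p of enrichment over input, with an upper limit of 400, and the authors' log2 fold over input. These meanings were read from the values, since the lists have no header. The −log10 p was 0 in every cluster with a negative fold, so the p is one-sided and carries nothing on depletion. How the authors combined the replicates into the series-wide list is not given in the sources used here. All 25 chromosomes' clusters ended within the hg19 chromosome lengths of GenomeInfoDb 1.38.1, and 14 chromosomes had a cluster beyond the end of hg38. Starts were converted to 1-based positions.

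Clusters with a −log10 p of at least 3 and a log2 fold of at least 3 (8-fold) were called enriched. These thresholds are in common use for the assay and were set before the data were examined, as were the comparison of the replicates and the description of the series-wide list. The authors' p-values compare 1 library with 1 input per cluster and were used only to filter within a list. Clusters of both replicates were called overlapping when they shared at least 1 base on 1 strand (bedtools 2.31.1), and the partner with the longest overlap was taken. For each series-wide region, the log2 fold of a replicate is that of the cluster with the longest overlap, and the mean and SD are over the 2 replicates. Enriched status was compared with Fisher's exact test, 2-sided. Odds ratios have 95% Wald intervals and shares have 95% Wilson intervals. These intervals treat clusters or loci as independent and cover counting error only. Where a share is 0, the largest share it allows is given as 3 counts of the total. Read depth is unknown, because the lists hold ratios and no reads, so no interval for a single fold can be given.

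The tests planned on annotated regions, on 29 gene lists and 2 unions of lists, on positions within transcripts and on base composition need a gene annotation or a sequence of hg19. None was used here, no coordinates were converted between builds, and no gene is named. Under the rule written for this case before the data were examined, the 10 series-wide regions with the largest lower value of both replicates are named by position. Other regions, loci and bands that are named were chosen after their values were seen.

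Analyses of loci, chromosomes, bands and the mitochondrial chromosome were chosen after seeing the data. A locus is a run of clusters of both replicates on 1 strand, ended by a gap of more than 5 kb. It stands in for a transcript but can join neighbouring genes or split 1 gene. Position within a locus runs from 0 at the 5′ end to 1 at the 3′ end. In loci with at least 5 intervals, the mean position of regions was compared with that of clusters enriched in neither replicate, by a 2-sided sign-flip permutation test over loci with 100000 resamples. The same test compared the mean log2 fold, and the percent of clusters below input, of the 3′ and 5′ sides of loci. Loci with and without a region were compared between each chromosome and all others with Fisher's exact test, with Benjamini-Hochberg adjustment over 25 chromosomes. Cytogenetic bands with at least 20 loci were treated in the same way over 643 bands, with hg19 bands from circlize 0.4.16. A logistic model with log2 cluster number and log2 locus length was fitted in statsmodels 0.14.6. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

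The position test and the test of chromosome intervals were tried on simulated data, and the other tests were not. With enriched clusters of replicate 1 redrawn at random within their loci, among 44346 clusters, the position test called 5% of 100 draws. These draws compared redrawn with remaining replicate 1 clusters, and not series-wide regions with clusters enriched in neither replicate. With enriched clusters drawn up to 3 times as often at the 3′ end, it called 100% of 20 draws. The interval test was run on 160 chromosome intervals in 20 draws, with loci holding a region planted at 15% in some intervals against 5% in the others. It called 84% of the planted intervals and 0.167% of the others. Each of these intervals held at least 100 loci, so the rates do not describe bands with fewer loci, down to the minimum of 20. Loci were drawn independently at flat rates, while in the data the share with a region rose with cluster number. Calls that come from differences in cluster number are therefore not covered by these rates. Alternatives covered the fold and p thresholds, cluster width, the overlap that counts as shared, the base replicate, the source of the regions, the gap between loci and the use of 1 replicate alone.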

Results

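LARP4 is an RNA-binding protein of the La-related family, and the series set out to find the RNAs it binds in HEK293 cells, with mRNAs of the nuclear genome that encode mitochondrial proteins as its named interest. Both LARP4 eCLIP replicates were read as log2 folds over size-matched input. Replicate 1 held 171755 clusters covering 9.38 Mb, and replicate 2 held 191899 clusters covering 10.4 Mb. Median cluster width was 51 and 50 bases. The number of reads behind a cluster is unknown. All positions are hg19, counted from 1.

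LARP4 eCLIP gave strong enrichment over input at a small part of its clusters in both replicates. Enriched clusters, with a log2 fold of at least 3 and a −log10 p of at least 3, numbered 8613 in replicate 1, or 5.01% (Wilson 95% interval 4.91 to 5.12). In replicate 2 they numbered 10551, or 5.50% (5.40 to 5.60). The median log2 fold over all clusters was 1.28 in replicate 1 and 1.30 in replicate 2, with middle ranges of 0.53 to 2.04 and 0.49 to 2.01. The highest folds were 8.05 and 7.92. Clusters below input made up 11.6% and 11.2% of the lists. The counts rest on the threshold: at a log2 fold of at least 4 they were 2515 and 3134, and at a log2 fold of at least 1 they were 24037 and 26225.

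Clusters enriched in one culture were mostly enriched in the other where both had a cluster. Of the replicate 1 clusters, 77005 (44.8%) overlapped a replicate 2 cluster. Among these, 5011 were enriched in both replicates, 2504 in replicate 1 alone, 3935 in replicate 2 alone and 65555 in neither. Of the clusters enriched in replicate 1, 66.7% (65.6 to 67.7) were also enriched in replicate 2, against 5.66% (5.49 to 5.84) of those not enriched in replicate 1. The odds ratio was 33.3 (31.5 to 35.3), with a Fisher's exact p too small to be represented. At a log2 fold of at least 4 in both replicates, the recurring share was 54.3% and the odds ratio 56.9. Across overlapping clusters, Pearson's r of the log2 folds was 0.74 and Spearman's rho 0.67, and the SD of a single replicate's value was 0.67. These values are across clusters, which are not independent replicates.

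The authors' series-wide list held 7153 regions, 3790 on the plus and 3363 on the minus strand, with a median width of 64 bases and 479 kb in total. The authors' log2 fold in it had a median of 3.65 and a highest value of 7.21, and no value lay below 3. All regions overlapped a cluster in each replicate. An enriched cluster was present at 6044 regions in replicate 1, at 6468 in replicate 2 and at 5359 (74.9%) in both. The median log2 fold of the overlapping cluster was 3.57 in replicate 1 and 3.73 in replicate 2, and 75.8% of regions had replicates within 1 log2 unit of each other. Across regions Pearson's r was 0.36 and Spearman's rho 0.28, within a list already restricted to high folds. Only 35 regions (0.489%) overlapped a cluster on the opposite strand. With any overlapping partner counted, in place of the longest overlap alone, 5179 enriched replicate 1 clusters overlapped an enriched replicate 2 cluster, of which 5115 (98.8%) lay in the authors' list.

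**Figure D1:**
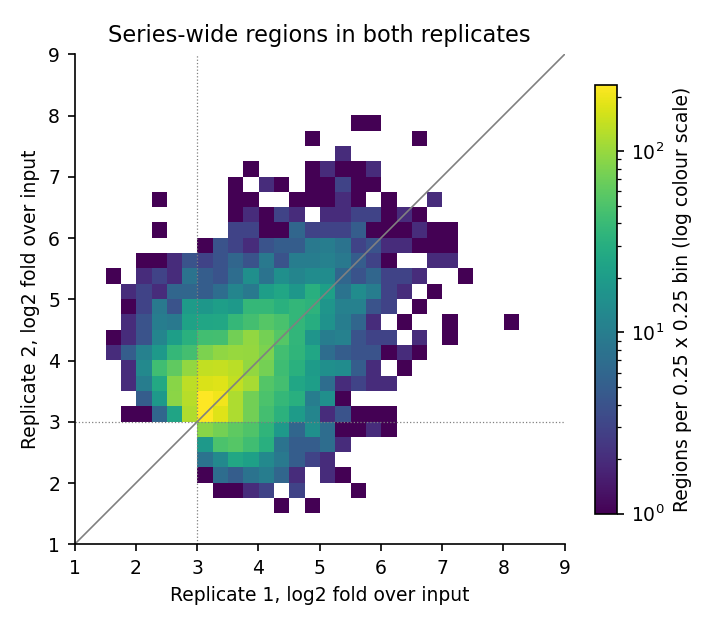
The log2 fold over input in replicate 1 (x axis) and replicate 2 (y axis) for the 7153 series-wide regions, binned, with colour on a log scale for the number of regions per bin, the line of equal values in grey and the threshold of 3 dotted. Regions were densest just above 3 in both replicates (medians 3.57 and 3.73), and none lay below 3 in both.

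The 10 regions with the highest lower value of both replicates lay in 6 loci on chromosomes 2, 12, 19 and 22. Each was at least 69.4-fold above input in both replicates. The highest was a region of 74 bases on the plus strand in 12q24.31, at chromosome 12, 120878449 to 120878522, with a log2 fold of 7.20 ± 0.72 (SD, n = 2), or 102.9-fold in the lower replicate. Its −log10 p was at the upper limit of 400 in both replicates. The other 9 named regions had −log10 p values between 22.9 and 92.8. The 12q24.31 region sat at the 3′ end of a locus from 120875925 to 120878522 that held 11 series-wide regions, and every one of its 22 clusters over both replicates was enriched. Within that locus the authors' log2 fold was 3.83 at the region nearest the 5′ end, 5.45 at 120876208 to 120876247 and 6.32 at 120878340 to 120878429, before 7.21 at the last region.

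**Figure D2:**
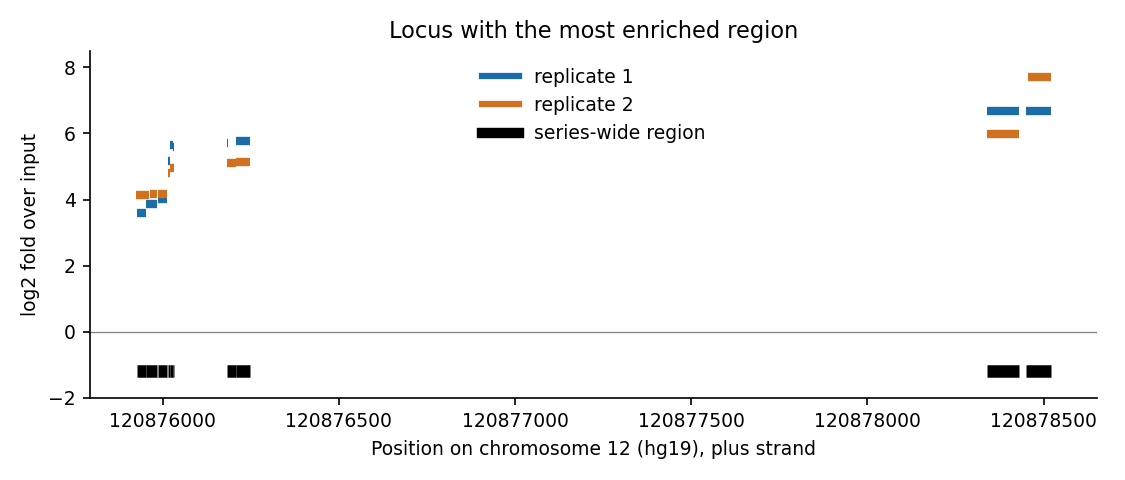
Clusters of the plus-strand locus in 12q24.31 on chromosome 12 (x axis, hg19 position in bases) by log2 fold over input (y axis), blue for replicate 1 and orange for replicate 2, with the 11 series-wide regions as black bars under the zero line, where their height carries no value. The fold ran from 3.59 and 4.12 in the 5′-most cluster of each replicate to 6.68 and 7.71 in the last.

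Band 19p13.3 held 6 of the 10 named regions, in 2 loci. On the plus strand, touching regions at chromosome 19, 4035497 to 4035528 and 4035529 to 4035573 had log2 folds of 6.76 ± 0.17 and 6.54 ± 0.48 (SD, n = 2), with the same replicate 1 cluster behind both, and a region of 41 bases at 4037052 to 4037092 had 6.27 ± 0.08. Their locus, 4028838 to 4038910, held 28 series-wide regions. On the minus strand, adjacent pieces at 5678599 to 5678643, 5678644 to 5678655 and 5678656 to 5678659 had log2 folds of 6.32 ± 0.28, 6.59 ± 0.67 and 6.76 ± 0.22, the first pair with 1 replicate 2 cluster in common. The named regions left were on the minus strand in 22q11.23 (chromosome 22, 24315957 to 24315988, 6.53 ± 0.26), the minus strand in 12q24.31 (chromosome 12, 123994613 to 123994729, 6.39 ± 0.14) and the plus strand in 2q21.1 (chromosome 2, 130948073 to 130948092, 6.33 ± 0.08). Position in the locus (0 at the 5′ end, 1 at the 3′ end) was 0.009 for the 22q11.23 region and 0.19 for the 2q21.1 region. It was 0.99 for the plus-strand 12q24.31 region, and the other named regions lay between 0.64 and 0.92. With 2 replicates and SDs of up to 0.72, the order among the 10 regions was not tested.

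Series-wide regions lay in 2232 loci. These were 5.05% of all 44219 loci and 7.90% of the 28261 loci with a cluster in both replicates. The 12309 loci of a single cluster cannot hold a region, since every region overlaps a cluster in each replicate. A single region was found in 968 loci, while 136 loci with at least 10 regions held 1992 of them (27.8%). The locus with the most, on the plus strand of 21q22.3 (chromosome 21, 44074047 to 44115714), had 52 regions with a mean log2 fold of 4.25 ± 0.09 (SD, n = 2). It was followed by 22q13.31 (chromosome 22, plus strand, 47507754 to 47571113) with 42 regions at 3.93 ± 0.03, and 17q21.33 (chromosome 17, plus strand, 49230948 to 49249054) with 33 at 3.63 ± 0.22. Next came 19q13.33 (chromosome 19, minus strand, 49110193 to 49122434) with 29 at 3.95 ± 0.28 and the plus-strand 19p13.3 locus above with 28 at 4.81 ± 0.12. Loci with a region were longer, with a median of 6.55 kb against 1.33 kb, and held a median of 20 clusters over both replicates against 3. The share of loci with a region was 0.955% at 2 to 5 clusters, 13.1% at 11 to 20 and 33.8% above 50.

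Enriched regions lay towards the 3′ ends of loci. In 1983 loci, series-wide regions had a mean position of 0.705, where 0 is the 5′ and 1 the 3′ end, and clusters enriched in neither replicate had 0.507. The difference was 0.198 (95% interval 0.184 to 0.213), with a sign-flip permutation p of 1e-05, the smallest the resamples can give, and 75.4% of the loci had the same direction. In these loci, 51.2% (50.0 to 52.5) of the 6404 regions lay in the last 20% of the locus length, against 25.8% (25.4 to 26.2) of the not-enriched clusters. The first 20% held 16.4% of the regions and 22.2% of the not-enriched clusters. From enriched and not-enriched clusters of replicate 1 alone the difference was 0.161, and of replicate 2 alone 0.131, against which the series-wide value is more than 1.5 times as large in the latter case. At a log2 fold of at least 4 it rose to 0.311.

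The same direction was present without any threshold. The mean log2 fold of clusters on the 3′ side of the locus midpoint was 1.33 against 1.19 on the 5′ side in replicate 1, a difference of 0.142 (0.125 to 0.160) over 9903 loci. In replicate 2 it was 1.28 against 1.16, a difference of 0.115 (0.098 to 0.132) over 11080 loci. Both had a sign-flip permutation p of 1e-05, the smallest possible, and 58.0% and 57.1% of loci were higher on the 3′ side. With a gap of 1 kb between loci the differences were 0.081 and 0.070, in the same direction. The enriched share was 12.9% and 13.7% in the last of 10 equal bins of locus length, against 4.72% and 5.79% in the first and 3.54% and 4.11% in the lowest, the bin from 0.2 to 0.3. The mean log2 fold was also higher in the first bin than in that bin, at 1.21 and 1.20 against 1.09 and 1.04. It was lower than in the bin from 0.8 to 0.9, at 1.31 and 1.26. The bins do not hold the same loci. The first had 8629 and 9902 loci and the last 8555 and 10140, against 4920 and 5631 in the bin from 0.2 to 0.3.

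**Figure D3:**
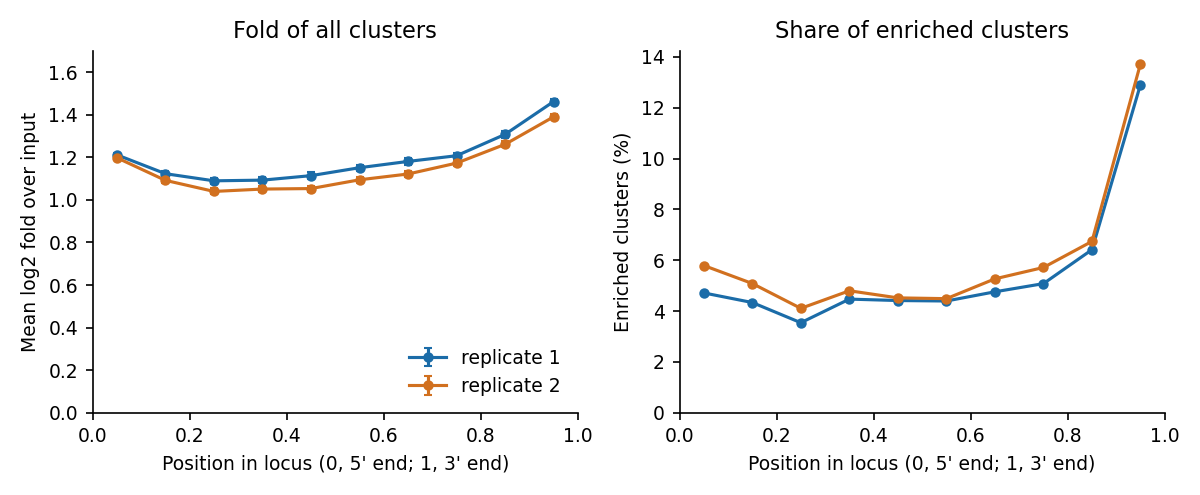
Mean log2 fold over input of all clusters (left) and percent of enriched clusters (right) in 10 equal bins of position in the locus, from the 5′ end at 0 to the 3′ end at 1 (x axis), for replicate 1 in blue and replicate 2 in orange. Error bars on the left are the standard error over loci, and the end bins hold more loci than the others. The last bin was highest in both replicates, with mean log2 folds of 1.46 and 1.39 and enriched shares of 12.9% and 13.7%.

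Loci on chromosome 19 held a series-wide region more often than loci elsewhere. They did so in 280 of 1682 loci, or 16.6% (14.9 to 18.5), against 4.59% on all other chromosomes. The odds ratio was 4.15 (3.62 to 4.76), with a Benjamini-Hochberg adjusted Fisher's exact p of 1.02e-70. Chromosome 19 carried 1183 regions, 16.5% of the list, but 6.50% and 6.18% of all clusters in replicates 1 and 2. Its clusters were enriched in 11.4% and 12.7% of cases. Among loci with a cluster in both replicates the shares were 22.2% and 7.23%, with an odds ratio of 3.67 (3.19 to 4.22). With cluster number and locus length in a logistic model the odds ratio was 2.43 (2.05 to 2.88).

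Of 25 chromosomes tested, 7 were higher than the others at an adjusted p under 0.05, 10 were lower and 8 did not pass. After chromosome 19, the shares were 10.2% on chromosome 22 (odds ratio 2.19, adjusted p 7.85e-10) and 8.73% on chromosome 17 (1.87, adjusted p 6.68e-13), and chromosomes 11, 16, 20 and 21 were also higher. The lowest shares among those past the threshold were 1.34% on chromosome 13 (odds ratio 0.25, adjusted p 8.51e-10), 1.58% on chromosome 18 (0.30, adjusted p 2.83e-09) and 1.83% on chromosome 4 (0.34, adjusted p 2.39e-13). Cluster number and locus length were not adjusted for in these tests.

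**Figure D4:**
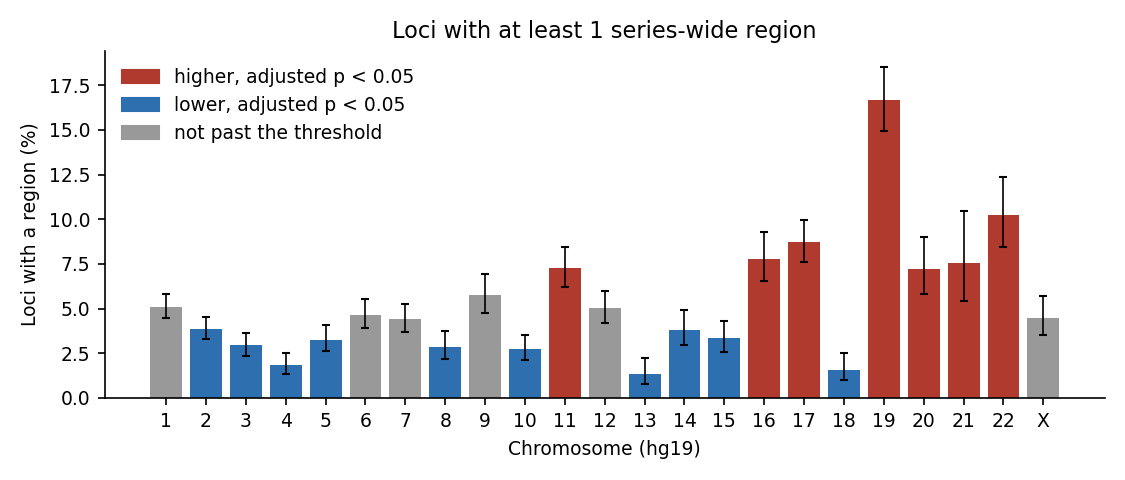
Percent of loci with at least 1 series-wide region (y axis) on chromosomes 1 to 22 and X (x axis), with Wilson 95% intervals, red for chromosomes higher than all others at an adjusted p under 0.05, blue for lower and grey for those that did not pass. Chromosome 19 stood at 16.6%, followed by chromosome 22 at 10.2%, and chromosome 13 was lowest at 1.34%.

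Among 643 bands, 49 had a higher share of loci with a region than the rest of the genome and 5 a lower one, after Benjamini-Hochberg adjustment of Fisher's exact p. Of the 49, 8 were on chromosome 19 and 36 were Giemsa-negative, the stain class of light bands. Giemsa-negative bands held 25345 of all 44219 loci. The number of Giemsa-negative bands among the 643 was not set against the 36, so this count shows no effect of stain class. Band 19p13.3 had a region in 67 of 237 loci (28.3%, odds ratio 7.61, adjusted p 7.84e-29). The highest odds ratio among the bands with the smallest p-values was in 6p21.33, with 26 of 58 loci (44.8%, 15.5, adjusted p 2.45e-16). Bands 11q13.1, 19q13.33, 17q25.3, 16p13.3 and 9q34.3 followed in order of p-value, with shares of 18.5% to 29.1%. Some bands with larger p-values had larger shares than these, such as 12q13.2 at 34.5%. The 5 lower bands were 1p31.1 with a region in 0 of 144 loci (adjusted p 0.0142), 2p21 with 1 of 185 (0.0175), 18q11.2 with 0 of 130 and 12q12 with 0 of 132 (both 0.0294), and 1p31.3 with 1 of 168 (0.0470). The counts of 0 allow shares of up to 2.08% in 1p31.1, 2.31% in 18q11.2 and 2.27% in 12q12. Of these bands, 2p21 and 18q11.2 were Giemsa-negative. Each share and limit counts all loci of a band, also those of a single cluster, which cannot hold a region. Cluster number and locus length were not adjusted for in the band tests.

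Clusters of the mitochondrial chromosome had lower folds than nuclear clusters and lay on both sides of the input level. Their median log2 fold was −0.11 in replicate 1 and 0.14 in replicate 2, with middle ranges of −1.21 to 0.59 and −1.10 to 0.80, against medians of 1.28 and 1.30 for nuclear clusters. The −log10 p was at its limit of 400 in 22 of 174 and 37 of 186 of them, with log2 folds of up to 1.59 and 1.55, and in 503 and 525 clusters of the whole lists. In replicate 1, 1 of 174 mitochondrial clusters was enriched (0.575%), against 5.02% of nuclear clusters, with an odds ratio of 0.11 and a Fisher's exact p of 0.00257. In replicate 2 none of 186 was enriched, a count of 0 that allows a share of up to 1.61% when 3 counts are taken as the limit, against 5.50% of nuclear clusters (Fisher's exact p 6.23e-05). The series-wide list held 1 region there, on the minus strand at 5829 to 5856, with a log2 fold of 3.05 ± 0.25 (SD, n = 2). At a log2 fold of at least 1 with the same limit on p, the difference was no longer present. The odds ratios were 1.03 (0.675 to 1.58) and 1.22 (0.822 to 1.80), with Fisher's exact p of 0.828 and 0.336. At a log2 fold of at least 1 and any p, 14.4% and 16.7% of mitochondrial clusters passed, against 59.4% and 60.9% of nuclear clusters (odds ratios 0.115 and 0.128). The mitochondrial clusters lay in 3 loci, with 167 of 174 and 177 of 186 on the plus strand. Fisher's exact test treats them as independent, which neighbouring clusters of so few loci are not, so its p-values overstate the evidence.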

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

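Clusters far below input were looked at only after the replicates had been described, and the comparisons above use none of them as a result. A log2 fold of −3 or lower was present in both replicates at 168 overlapping clusters in 107 loci. The 77005 overlapping clusters included 216 such clusters in replicate 1 and 229 in replicate 2, and 0.642 would be shared if the replicates were independent, so the low values recurred at the same positions. They stood out because they are a signal outside the enriched set. Ordered by the higher value of both replicates, the lowest was on the minus strand of 11p15.4 (chromosome 11, 2984999 to 2985123), with log2 folds of −5.70 and −6.54. Next, at mean log2 folds of −5.53, −5.45, −5.39 and −5.44, came 1p34.1 (chromosome 1, minus strand, 45187514 to 45187531), 9q33.3 (chromosome 9, minus strand, 130210789 to 130210808), 13q12.2 (chromosome 13, plus strand, 27829595 to 27829630) and the plus strand of 11p15.4 (8707051 to 8707111). Chromosome 1 held 33 of the 168 and chromosome 19 held 6. Of all clusters, these chromosomes held 9.22% and 6.50% in replicate 1 and 9.19% and 6.18% in replicate 2. A series-wide region was also present in 23 of the 107 loci, against 7.90% of all loci with a cluster in both replicates. These counts were not tested against those shares. The 107 loci were not matched on cluster number, and loci with more clusters held a region more often. Over all loci the share was 13.1% at 11 to 20 clusters and 33.8% above 50, so whether locus size accounts for the 23 of 107 stays open. The authors' −log10 p is 0 for all 168 clusters, as for every cluster with a negative fold, so no test of depletion was made. What RNAs these are was not analysed here.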

How the results depend on the processing

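Of 60 alternatives run, 2 put a value on the other side of no difference, with intervals that include no difference. Another 15 moved a value and 43 did neither. A tested value counted as kept by its direction and side of the threshold, whatever its size, a count within 1.5 times, a share inside its interval and r to 2 decimals. Alternatives on loci, chromosome 19, the mitochondrial chromosome and merged regions were chosen after seeing the data. Enriched clusters in replicates 1 and 2 numbered 24037 and 26225 at a log2 fold of at least 1, 18943 and 21707 at 2, 2515 and 3134 at 4, and 4605 and 5531 at a −log10 p of at least 10, as looser or stricter thresholds must give. The percent of enriched clusters recurring in the other replicate was 82.2 at a log2 fold of at least 1, 77.8 at 2 and 54.3 at 4 (odds ratios 39.2, 31.6 and 56.9), 56.9 with replicate 2 as base and 69.5 with a reciprocal overlap of at least 50%, where Pearson's r was 0.77. The series-wide list had 2181 regions at a log2 fold of at least 4. The mitochondrial odds ratio was 1.03 and 1.22 at a log2 fold of at least 1, with intervals that include 1. At a log2 fold of at least 2 it was 0.0466 and 0.172. At a log2 fold of at least 1 and any p it was 0.115 and 0.128, so the loss of the difference needed both the lower fold and the limit on p. From 1 replicate alone, the chromosome 19 odds ratio was 3.60 to 3.69 and the shift in position 0.131 to 0.161.

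No paired analysis was possible because the inputs enter only within each replicate's ratio, so a replicate block can be neither added nor removed. A test of the 2 ratios per region against 0 was not run. The alternatives planned for region shares, gene list enrichment with and without matched abundance, mean enrichment of each list, position within transcripts and base composition were not run, since no annotation or sequence of hg19 was used here. Unknown read depth limits every fold, and a cluster with few input reads differs from a deep one only through its p.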

Other observations

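The patterns in this part were found in these data, and the test of the strands, the shares by stain class and the last 2 comparisons of touching regions were chosen after their results were seen. Light Giemsa bands held regions more often than dark ones: 6.0% of loci in Giemsa-negative bands and 7.80% in the lightest positive class (25) held a region, against 3.43%, 1.65% and 1.57% in classes 50, 75 and 100. Without chromosome 19 the first pair of values was 5.57% and 6.17%. The differences between stain classes were not tested, and cluster number and locus length were not adjusted for.

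Series-wide regions lay towards the 3′ ends of loci. An artefact of genome coordinates would shift the strands in opposite directions, and the mean shift was 0.201 on the plus and 0.196 on the minus strand, which argues against it; how clusters were joined into loci stays open, with shifts of 0.164 and 0.188 at gaps of 1 kb and 10 kb. Deeper coverage that only helps clusters pass the p threshold would leave the folds level, and the lower bound of the smaller fold difference between the 3′ and 5′ sides was 0.098, which argues against that as the whole cause. Shallow coverage nearer the 5′ end could also limit the fold a cluster can reach, and this stays open: the percent of clusters below input, 3′ minus 5′ side, was −0.597 (−1.12 to −0.073) in replicate 1 but −0.034 (−0.509 to 0.441) in replicate 2. No biological explanation was tested, since the design holds 1 condition.

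Chromosome 19 loci held regions more often, and loci there have more clusters, with a median of 6 against 3. With cluster number and length in the model the odds ratio was 2.43, so these measures may account for part of the 4.15. The cluster number also includes the enriched clusters themselves, so how much of the drop is due to locus size cannot be told from this model. Both measures come from clusters and not reads, and read depth is unknown, so coverage as a cause of the rest stays open. Giemsa-negative bands hold 44.4% of chromosome 19 loci against 57.8% elsewhere. Within them the odds ratio was 4.26, which argues against band class as the cause for the loci in these bands. The lower percent does not mean darker bands, since leaving out chromosome 19 did not change the shares of the darker classes. It changed that of the lightest positive class from 7.80% to 6.17%. The odds ratio was not computed within that class, so band class stays open for chromosome 19 loci outside Giemsa-negative bands. GC content was not tested, as no hg19 sequence was used here, and stays open, as does any biological explanation.

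Of the series-wide regions, 3444 (48.1%) touched another, and merging left 5023 blocks, 3709 of them of 1 region and the largest of 15. A candidate explanation is that the segmentation divides 1 site into pieces. Touching neighbours then should have closer folds in the authors' list than neighbours apart, and the median absolute log2 difference was 0.244 in 2130 touching pairs against 0.307 in 2101 pairs up to 1000 bases apart, a difference of −0.063 (permutation p 1e-05, the smallest the resamples can give). Of the touching pairs, 85.6% overlapped a replicate cluster in common, which could draw their values together. Whether it does is unknown, since how the authors combined the replicates is not given. Without pairs that share a cluster, the median was 0.192 in 306 touching pairs and 0.305 in 2024 pairs apart. The difference was −0.113 (permutation p 2e-05). Against 499 pairs 1 to 20 bases apart, the difference for all touching pairs was −0.057 (permutation p 0.00037). A region can belong to more than 1 pair, so the pairs are not independent and these p-values may overstate the evidence. Reads that span a border could also bring touching values together and were not tested, so the number of separate sites stays open.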
